A study of Mus musculus with 12 samples.

How the data were processed

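Gene expression was measured by RNA sequencing of mouse primary bone marrow-derived macrophages, per the labels from wild-type animals. The labels give 4 groups of 3 libraries each: untreated control cells, cells given CS-PA/CNP, cells given PgLPS, and cells given both. The labels do not spell out either abbreviation, and neither is expanded here. They also give no dose or time. The words added and reversed below compare groups and do not state which agent came first. Per the labels' protocols, libraries were made from total RNA with selected fragments of 400 to 500 bp and 15 PCR cycles, and were read on a NovaSeq instrument. The strandedness of the libraries is not given in the sources used here, so reads of overlapping and antisense genes cannot be separated.

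The values used are the authors' deposited read counts per gene, whole numbers that were not normalized, in 1 table of 21899 genes with 12 columns of counts. The submitters' processing notes name cutadapt 1.15, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0, with no role or order. The deposited table also holds FPKM values, which were not used. They equalled the count scaled by gene length and library total for 100% of values at a relative tolerance of 1e-06, and so carry no further measurement. The genome build and annotation are not given in the sources used here. Of the Ensembl gene identifiers in the table, 21795 (99.5%) were found in the GENCODE annotation of GRCm38, and 99.8% of those were protein coding there. Only 2.34% of them had the same start and end as in that annotation, so chromosomes are given and coordinates are not. Symbols are those in the deposited table, where 42 genes share a symbol with another gene. Count columns were assigned to a group by the letters in their names, a reading that the labels do not spell out. L was read as PgLPS, LM as both agents, M as CS-PA/CNP and C as control. The replicate numbers in the sample titles could not be matched to those columns, so library numbers in the text are the numbers in the column names, which are not taken to pair libraries across groups.

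Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, called edgeR below. All 12 libraries entered 1 fit with a mean per group, TMM normalization and the filterByExpr filter by group, which kept 11656 genes holding 99.97% of the reads. Adjusted p-values are Benjamini-Hochberg (BH) values over the tested genes, with a threshold of 0.05, and all tests were 2-sided. There were 5 comparisons: PgLPS against control, both agents against PgLPS, CS-PA/CNP against control, both agents against control, and the interaction, which is the effect of CS-PA/CNP with PgLPS minus its effect without. An error after a log2 fold change is its standard error from that fit, with 3 libraries per group. Levels are CPM, counts scaled to the library total times its TMM factor, as mean ± SD over 3 libraries. The TMM factors were 1.15 to 1.16 in control, 1.11 to 1.12 with CS-PA/CNP, 0.853 to 0.875 with PgLPS and 0.890 to 0.901 with both. The labels call the libraries biological replicates, but nothing says that they came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

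A fold against a group with no reads was computed against 3 counts summed over the 3 libraries of that group and is written as a lower bound. With 1 to 3 reads in a group, the ratio of CPM is given with an exact 95% counting interval. These intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. With totals of 14992707 to 20082900 reads per library, each multiplied by its TMM factor, 3 reads over a group came to 0.0528 CPM in control, 0.0508 CPM with CS-PA/CNP, 0.0664 CPM with PgLPS and 0.0634 CPM with both.

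The design, 30 gene lists, the rule for named genes and the alternatives, except for those named as added, were fixed before the data were examined. Per comparison the rule takes the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the libraries compared. It leaves out symbols of the form Gm plus digits, Rik and other clone names, pseudogenes, immunoglobulin and T cell receptor segments and genes without a symbol. It adds up to 4 tested members with the smallest adjusted p from each described list, and Tnf, Il1b, Il6, Il10, Nos2 and Arg1 in every comparison. For the interaction it takes 6 genes per direction without the overlap condition. Genes named outside this rule are said to be so.

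The lists were pro-inflammatory cytokines, chemokines, NF-kB feedback genes, interferon-stimulated genes, Toll-like receptor signalling, inflammatory effectors of classical activation, alternative activation and resolution, inflammasome and lytic cell death, NRF2 antioxidant targets, unfolded protein and integrated stress response, p53 targets, lysosome and phagocytic load, glycolysis and hypoxia response, cholesterol biosynthesis, lipid handling and LXR targets, cell cycle, MHC class I and MHC class II presentation, matrix proteases and inhibitors, osteoclast differentiation, blood pressure and vasoactive systems, growth and repair factors, macrophage identity, and markers of neutrophils, stromal cells and fibroblasts, T cells, B cells, dendritic cells, erythroid cells, and mast cells and basophils. Of 450 genes in the lists, 445 were in the table and 387 were tested; Cxcl11, Mx1, Mx2, Trac and Ighm were not in the table. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with BH adjustment over the lists of a comparison. The 29 lists with at least 3 tested members were tested. A list median takes genes without reads in a group at their floor. Calls by the same test with a correlation estimated from the data are given where they differ. Members of families with similar sequences, such as the Gbp, Saa, Ifi200, Serpinb, Ccl, H2, Oasl and Apol9 genes, have uncertain counts, because the treatment of reads shared between copies is not given in the sources used here.

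The gene and list tests were tested on simulated counts with 200 changed genes per comparison. Of genes changed 2-fold, 92% were recovered for PgLPS against control among 11544 genes, 90% for both against PgLPS among 11538, 90% for CS-PA/CNP against control among 11530, 90% for both against control among 11524 and 84% for the interaction among 11530. False calls made up 3.23%, 1.94%, 4.40%, 7.83% and 8.96% of the calls in the same order. A list raised in simulation was called by the test with a preset correlation, the test with an estimated correlation and fry, and 0 of the other lists were. Genes were simulated independently of each other, so this says nothing on false list calls among correlated genes or on the preset correlation. The alternatives tried were DESeq2 size factors, library totals in place of TMM, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, only the groups compared, a 2-fold minimum, other list tests and leaving out each library. A replicate block by column number, and DESeq2 size factors and library totals for the list tests, were added after the data were seen. Ranges of an adjusted p over the alternatives leave out that block, which is given apart.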

Results

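Messenger levels were measured in mouse bone marrow-derived macrophages, a primary cell grown from marrow, in 12 libraries. The groups were untreated control, CS-PA/CNP, PgLPS, and PgLPS with CS-PA/CNP, with 3 libraries each. The series title places the experiment in work on a composite hydrogel for periodontitis and hypertension. The deposited counts summed to 15570148 to 17339556 reads per control library, 16130784 to 20082900 with CS-PA/CNP, 14992707 to 19252143 with PgLPS and 16301947 to 19422021 with both. Between 13169 and 13511 genes had reads in a library, and the 10 genes with most reads held 10.5% to 12.2% of them. Mitochondrial genes held 1.62% to 1.82% of reads in control, 1.60% to 1.74% with CS-PA/CNP, 1.07% to 1.17% with PgLPS and 1.21% to 1.28% with both. The first principal component of the tested genes carried 83.0% of the variance and ordered the groups as control (−71.4 to −70.3), CS-PA/CNP (−56.5 to −54.4), both (48.5 to 53.1) and PgLPS (74.1 to 75.5). No 2 libraries of a group agreed within sampling noise, with a chi-square per gene of 2.75 to 17.0.

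The comparison of PgLPS with control asks how these macrophages responded to PgLPS alone. The largest rises included genes of acute-phase and cytokine proteins. Saa3, an acute-phase protein, went from 1.06 ± 0.48 CPM in control to 13137 ± 2341 CPM with PgLPS (SD, n = 3), a log2 fold change of 13.59 ± 0.44 (edgeR BH-adjusted p = 2.0e-15). Il1b (ENSMUSG00000027398, chromosome 2), which encodes interleukin-1 beta, rose by 12.69 ± 0.23 from 0.454 ± 0.33 to 3064 ± 105 CPM (edgeR BH-adjusted p = 3.5e-19). Serpinb2, an inhibitor of plasminogen activators, had 0 reads in control and 12612 with PgLPS, at least 5290-fold higher. Nptx1, a pentraxin, fell by 8.01 ± 0.21 from 87.7 ± 9.4 to 0.336 ± 0.18 CPM (edgeR BH-adjusted p = 7.5e-17).

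Of 11656 genes, 3750 rose and 3683 fell, and 1372 and 1468 of these changed at least 2-fold. The largest rises also included the chemokine gene Ccl5 at 11.95 ± 0.23, the guanylate-binding protein gene Gbp5 at 10.66 ± 0.19 and Acod1, the itaconate-producing enzyme, at 10.55 ± 0.15. Gbp5 stood at 11.50 without control library 3. Cxcl3, a neutrophil-attracting chemokine, rose by 10.74 ± 0.35, with 12.73 without control library 3 and 10.14 without control library 1. The integrin gene Itgb8 had 0 reads in control and 1171 with PgLPS, at least 491.2-fold higher. Csf3, the granulocyte growth factor, had 1 read in control and 2263 with PgLPS, a ratio of 2848 (95% counting interval 510.6 to 112528). The largest falls beside Nptx1 were in the transporter gene Slco2b1 (−7.15 ± 0.27), Klhl3 (−6.88 ± 0.37), Tox2 (−6.45 ± 0.36), Lama3 (−6.43 ± 0.37), Plekhh2 (−6.07 ± 0.36), Dmpk (−5.98 ± 0.36) and Rasgrp3 (−5.60 ± 0.14). Several of these had few reads with PgLPS: Slco2b1 stood at −6.56 without PgLPS library 2 and −7.88 without library 3, Lama3 at −7.85 without library 1 and −5.79 without library 3, and Plekhh2 at −6.66 without library 2.

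Among the genes followed in every comparison, Tnf (ENSMUSG00000024401, chromosome 17), the tumour necrosis factor gene, rose from 42.5 ± 2.1 to 236 ± 29 CPM, by 2.47 ± 0.08 (edgeR BH-adjusted p = 4.5e-15). Il6 (ENSMUSG00000025746, chromosome 5) had 2 reads in control, both in library 3, and 2069 with PgLPS, a ratio of 1302 (359.9 to 10757). Nos2 (ENSMUSG00000020826, chromosome 11), the inducible nitric oxide synthase, had 3 reads in control, all in library 1, and 633 with PgLPS, a ratio of 265.5 (90.4 to 1291). Il10 (ENSMUSG00000016529, chromosome 1), an anti-inflammatory cytokine gene, rose by 2.24 ± 0.18 and Arg1 (ENSMUSG00000019987, chromosome 10), the arginase gene, by 5.64 ± 0.27.

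All 12 tested pro-inflammatory cytokine genes rose, as they did when adjusted over the list alone, with Il1a at 9.18 ± 0.18 (list median 5.49, camera BH-adjusted p = 2.9e-07). All 16 chemokine genes rose by either adjustment, among them Cxcl10 at 9.11 ± 0.20 (9.73 without control library 3), Ccl7 at 6.45 ± 0.17 and Cxcl2 at 5.45 ± 0.13 (list median 5.46, camera BH-adjusted p = 5.3e-10). All 27 interferon-stimulated genes rose by either adjustment, with Ifit1 at 8.21 ± 0.11, Rsad2 at 8.20 ± 0.10 and Irf7, a transcription factor of the interferon response, at 6.57 ± 0.08 (list median 6.57, camera BH-adjusted p = 1.6e-19). Of 19 NF-kB feedback genes, 18 rose and 1 fell, in both adjustments, with Socs3 at 9.45 ± 0.13 and the NF-kB inhibitor Nfkbia at 2.86 ± 0.07 (camera BH-adjusted p = 5.3e-10). Of 16 inflammatory effectors, 15 rose, and 1 was not called, in both adjustments, with the scavenger receptor Marco at 8.22 ± 0.11 (camera BH-adjusted p = 9.1e-11). Of 18 genes of Toll-like receptor signalling, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone, with Irak3 at 4.02 and Tlr2 at 2.84 (camera BH-adjusted p = 2.7e-05). Of 14 inflammasome and lytic death genes, 12 rose and 1 fell by either adjustment, with the necroptosis effector Mlkl at 4.71 and the inflammatory caspase Casp4 at 3.71 (camera BH-adjusted p = 7.4e-06).

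All 25 cell cycle genes fell by either adjustment, among them the replication helicase subunits Mcm5 at −3.43 and Mcm2 at −3.07 ± 0.09 (list median −2.41, camera BH-adjusted p = 4.6e-11, and camera BH-adjusted p = 0.0538 with an estimated correlation). All 12 MHC class I genes rose, with the peptide transporter Tap1 at 3.40 ± 0.08 (camera BH-adjusted p = 4.5e-08, adjusted p = 0.106 with an estimated correlation), and 7 of 8 MHC class II genes rose, with H2-Ab1 at 1.57 (camera BH-adjusted p = 0.00484, adjusted p = 0.184 with an estimated correlation); counts adjusted over the list alone were the same. Of 12 growth and repair factors, 1 rose and 9 fell in both adjustments, with the riser Thbs1, thrombospondin, at 5.79 ± 0.19 and Pdgfb at −3.31 ± 0.08. That list gave camera BH-adjusted p = 0.0112, adjusted p = 0.0538 with an estimated correlation and 0.127 with library totals. Of 6 stromal marker genes 5 rose, or 6 adjusted over the list alone, with Pdgfrb at 4.31 ± 0.45 (5.03 without control library 3) and the collagen gene Col1a1 at 3.48 ± 0.78 (1.61 without PgLPS library 1; camera BH-adjusted p = 0.0844). Some lists that were not called held changes of both signs: in glycolysis and hypoxia response 13 of 20 rose and 4 fell, with Pfkfb3, an activator of glycolysis, at 4.23 ± 0.08 and Vegfa at −2.36 ± 0.11 (camera BH-adjusted p = 0.0844). Of 16 NRF2 targets 12 rose and 3 fell, or 12 and 4 adjusted over the list alone, with the glutathione reductase Gsr at 1.91 ± 0.06 (camera BH-adjusted p = 0.0541). Of 15 alternative activation genes, 8 rose and 5 fell in both adjustments, with the interleukin-1 receptor antagonist Il1rn at 6.16 ± 0.08 and the nuclear receptor Pparg at −3.41 ± 0.12 (camera BH-adjusted p = 0.603). Of 15 stress response genes 9 rose and 3 fell in both adjustments, with Xbp1 at 0.58 and Sdf2l1 at −0.77 (camera BH-adjusted p = 0.188).

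Of the calls, 50.5% were rises, and with library totals in place of TMM the share was 21.8%. For 1043 of the genes called with TMM, library totals gave a fold change of the opposite sign, whether called or not. Library totals moved the median log2 fold change of all genes by −0.41 in this comparison, and changes are given relative to the TMM scale.

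**Figure D1:**
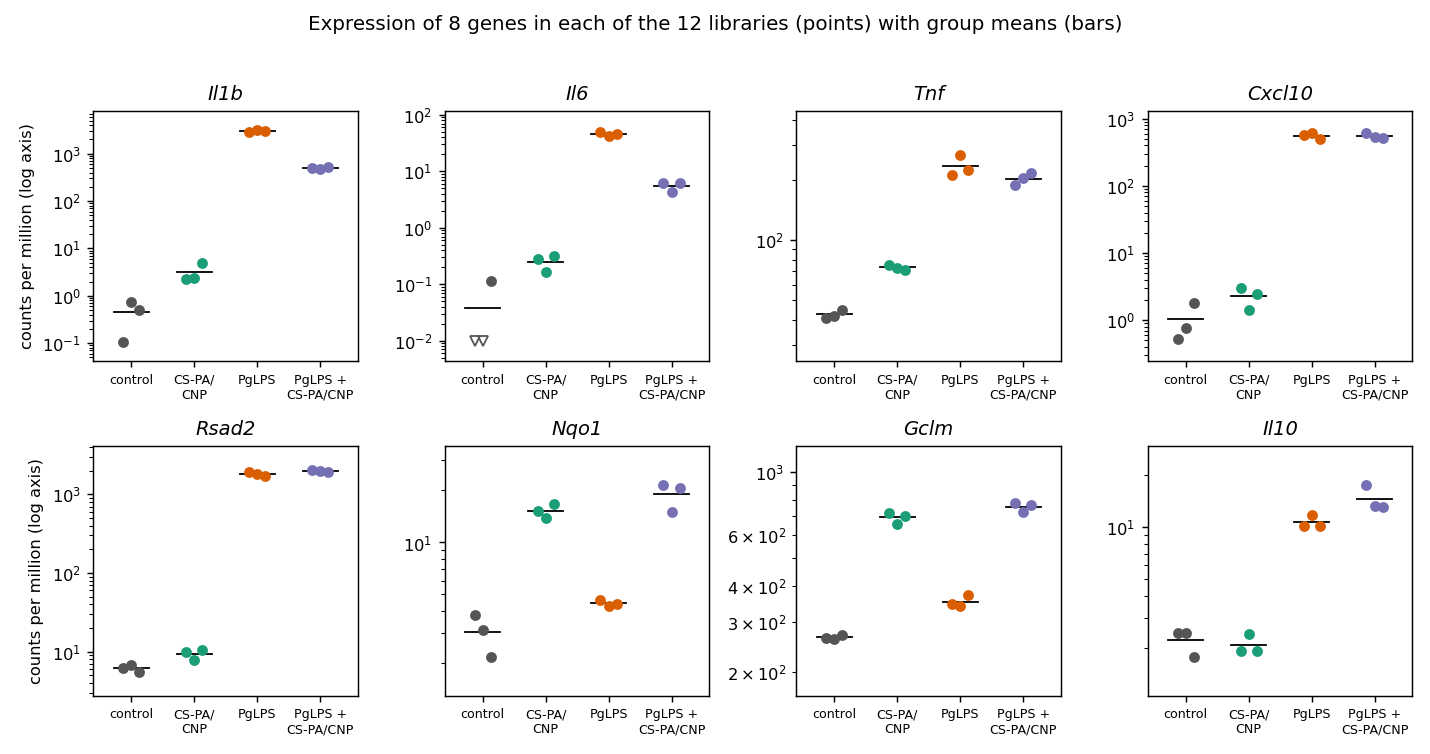
Level of 8 genes in CPM on log axes, 1 point per library and a bar at the mean of each group of 3 libraries; open triangles at 0.01 mark 2 control libraries with 0 Il6 reads. Il1b lay at 3064 ± 105 CPM with PgLPS and 499 ± 28 CPM with both (SD), while Rsad2 lay at 1831 ± 112 and 1985 ± 60.2 CPM.

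The comparison of both agents with PgLPS asks what CS-PA/CNP changed in cells that also received PgLPS. The cytokine genes Il1b and Il6 were lower with both agents than with PgLPS, and the antioxidant gene Nqo1 was higher. Il1b fell by 2.62 ± 0.12, from 3064 ± 105 to 499 ± 28 CPM (SD, n = 3; edgeR BH-adjusted p = 5.0e-11). Il6 fell by 3.06 ± 0.16, from 46.0 ± 4.6 to 5.56 ± 1.1 CPM (edgeR BH-adjusted p = 1.5e-10). Nqo1, a quinone reductase and NRF2 target, rose by 2.10 ± 0.18, from 4.44 ± 0.19 to 19.1 ± 3.5 CPM (edgeR BH-adjusted p = 6.3e-08).

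In all, 1098 genes rose and 1170 fell, and 152 and 203 of these changed at least 2-fold. The other largest falls were in Draxin (−3.48 ± 0.44), Serpinb2 (−3.33 ± 0.16), Thbs1 (−2.93 ± 0.16), Csf3 (−2.58 ± 0.19), Tnfsf15 (−2.43 ± 0.34) and Il1a (−2.41 ± 0.11). The other largest rises were in Fcrl1 (2.05 ± 0.19), the acetyl-CoA synthetase Acss2 (2.02 ± 0.16), Cgnl1 (1.95 ± 0.16), Angptl2 (1.94 ± 0.08), Zfyve28 (1.90 ± 0.25), Serpinb6b (1.76 ± 0.12) and Nav2 (1.71 ± 0.12). Nos2 fell by 2.28 ± 0.24 (edgeR BH-adjusted p = 1.3e-06) and Arg1 by 1.02 ± 0.19 (edgeR BH-adjusted p = 6.2e-04). Tnf had a log2 fold change of −0.22 ± 0.08 and was not called (edgeR BH-adjusted p = 0.0582, 0.0164 to 0.283 over the alternatives). It was called without PgLPS library 1 (edgeR BH-adjusted p = 0.0164) and without library 3 of both agents (edgeR BH-adjusted p = 0.0476), and by DESeq2 (BH-adjusted p = 0.0467) and edgeR with no filter (BH-adjusted p = 0.0437). Il10 rose by 0.45 ± 0.15 (edgeR BH-adjusted p = 0.0454, 0.0252 to 0.246 over the alternatives). That call was lost without PgLPS library 1 (0.124), PgLPS library 3 (0.140) or library 1 of both agents (0.246), as edgeR BH-adjusted p, with only the 2 groups in the fit (0.0566) and by DESeq2 (0.0578).

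Of 12 cytokine genes, 10 fell and 2 were not called, or 12 fell adjusted over the list alone (list median −1.97, camera BH-adjusted p = 2.7e-10). Of 16 inflammatory effectors 15 fell and 1 was not called, in both adjustments, with Slc7a2, an arginine transporter, at −2.32 ± 0.16 and the siderophore-binding protein Lcn2 at −1.98 ± 0.11 (camera BH-adjusted p = 2.7e-10). Of 19 NF-kB feedback genes 17 fell and 2 were not called, or 18 fell and 1 rose adjusted over the list alone, with Traf1 at −1.48 and Socs3 at −1.13 (camera BH-adjusted p = 8.3e-12). Of 16 chemokine genes 10 fell and 6 were not called in both adjustments, with Ccl22 at −1.28 and Ccl5 at −1.06 ± 0.12 (camera BH-adjusted p = 2.2e-04). Of 18 Toll-like receptor signalling genes 6 fell and 12 were not called, or 8 fell adjusted over the list alone, with the receptor genes Cd14 at −1.12 and Tlr2 at −1.01 (camera BH-adjusted p = 1.6e-04).

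Of 27 interferon-stimulated genes 11 fell and 16 were not called, or 12 fell and 2 rose adjusted over the list alone, with Gbp5 at −0.89 and Ifi205 at −0.82. Their median was −0.16 (camera BH-adjusted p = 0.00912, adjusted p = 0.183 with an estimated correlation). Rsad2, which was not among the 4 members the rule takes here, lay at 1831 ± 112 CPM with PgLPS and 1985 ± 60.2 CPM with both. Of 16 NRF2 targets, 13 rose, 1 fell and 2 were not called in both adjustments, with catalase (Cat) at 1.13 and Gclm, a subunit of the glutathione synthesis enzyme, at 756 ± 29.6 CPM with both against 353 ± 17.4 with PgLPS. The NRF2 list had a median of 0.66 (camera BH-adjusted p = 2.1e-10, adjusted p = 0.0572 with an estimated correlation). Of 19 cholesterol synthesis genes 10 rose and 9 were not called in both adjustments, with Dhcr7 at 0.86 and Sqle at 0.42 (camera BH-adjusted p = 5.7e-06). Of 15 stress response genes 8 rose and 7 were not called in both adjustments, with Sdf2l1 at 0.98 and the chaperone Hspa5 at 0.43 (camera BH-adjusted p = 3.1e-04, adjusted p = 0.0581 with an estimated correlation). In glycolysis and hypoxia response 11 of 20 fell and 1 rose, or 11 and 2 adjusted over the list alone, with Pfkfb3 at −1.97 ± 0.07 and Hif1a, the hypoxia-inducible factor, at −1.73 ± 0.10 (camera BH-adjusted p = 6.1e-04, adjusted p = 0.233 with an estimated correlation).

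Of 14 inflammasome genes 7 fell and 2 rose, or 8 and 3 adjusted over the list alone, with Nlrp3 at −1.17 ± 0.10 and Nlrp1b at 0.85. That list had camera BH-adjusted p = 0.0448, which became an adjusted p = 0.124 with an estimated correlation, 0.114 without PgLPS library 2 and 0.0887 without library 3 of both agents. Of 12 MHC class I genes 6 fell, or 8 adjusted over the list alone, with Tap1 at −0.32 (camera BH-adjusted p = 0.00188, adjusted p = 0.305 with an estimated correlation). Of 8 MHC class II genes 1 fell in both adjustments (camera BH-adjusted p = 0.251). Of 25 cell cycle genes 5 rose and 2 fell, or 7 and 2 adjusted over the list alone, with Pcna at 0.68 and Mki67 at −1.02 ± 0.09 (camera BH-adjusted p = 0.0656). Of 15 alternative activation genes 6 rose and 5 fell, or 6 and 6 adjusted over the list alone, with Pparg at 1.19 ± 0.13 and Il1rn at −1.63 ± 0.06 (camera BH-adjusted p = 0.580).

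PgLPS library 1 held 287 reads of the collagen gene Col1a1, against at most 57 in any other library. Of 6 stromal marker genes, 4 were lower with both agents than with PgLPS, or 5 adjusted over the list alone, with the receptor gene Pdgfrb at −2.20 ± 0.37 (camera BH-adjusted p = 0.0449, adjusted p = 0.381 with an estimated correlation). Without PgLPS library 1 that list had a camera BH-adjusted p of 0.150, without PgLPS library 2 0.0698, and without library 3 of both agents 0.0853. Of all calls, 48.4% were rises, and with library totals 61.4%.

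**Figure D2:**
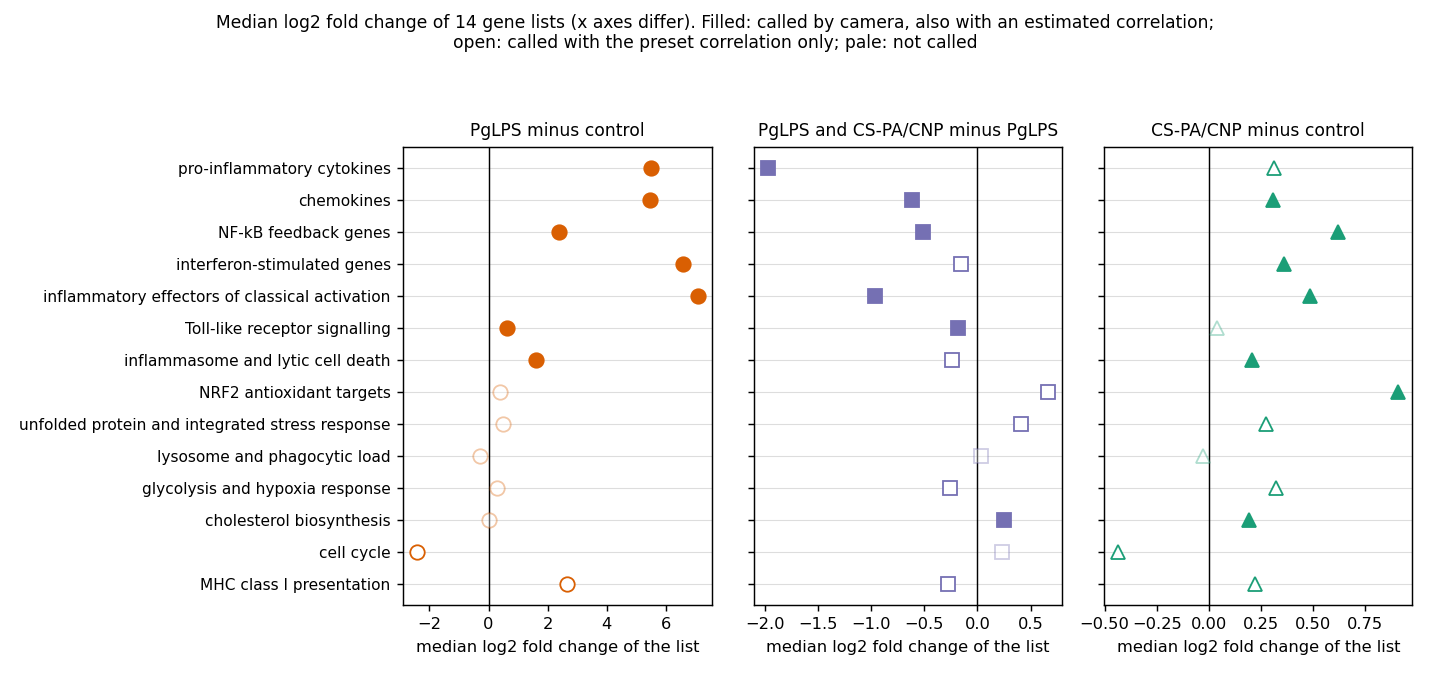
Median log2 fold change of 14 gene lists in 3 comparisons, with a separate horizontal axis for each; filled points were called with a preset and an estimated correlation, open points with the preset correlation only, and pale points were not called. The cytokine list lay at 5.49 for PgLPS against control and −1.97 for both against PgLPS, and the NRF2 list at 0.91 for CS-PA/CNP against control.

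PgLPS-responsive genes were then followed into the comparison of both agents with PgLPS. Of the genes changed by PgLPS, 1850 (24.9%) were called in the opposite direction when CS-PA/CNP was added. Of these, 1038 rose with PgLPS and were lower with both, among them Il1b, Il6 and Serpinb2, where independent lists would share 376. Another 812 fell with PgLPS and were higher with both, among them Plau, the urokinase gene, and Lipa, the lysosomal acid lipase gene, where independent lists would share 347. Plau went from 1139 ± 21.5 CPM in control to 44.2 ± 1.2 with PgLPS and 104 ± 4.9 with both. In the same direction as with PgLPS, 155 genes were higher in both comparisons and 35 lower in both, against 353 and 369.7 for independent lists. For 386 of the 1850 genes no difference from control was called with both agents. The median share of the PgLPS log2 change that was missing with both agents was 17.8% for the genes PgLPS raised and 22.8% for those it lowered. A change that was prevented and one that was turned back cannot be told apart here.

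The 2 comparisons share the PgLPS libraries with opposite sign. Unchanged groups were simulated in 20 sets, with the same mean in all groups and the totals and spread of these libraries. They gave a mean of 0.1 such genes. Without a PgLPS effect hardly any gene was called in them, so this count was fixed near 0 and decides nothing. The covariance of the fold changes was −0.0202 against −0.405 observed, and the correlation across genes −0.517 against −0.580 observed. The 3 PgLPS libraries were not split between the 2 comparisons, so part of the excess over independent lists can come from the shared libraries.

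**Figure D3:**
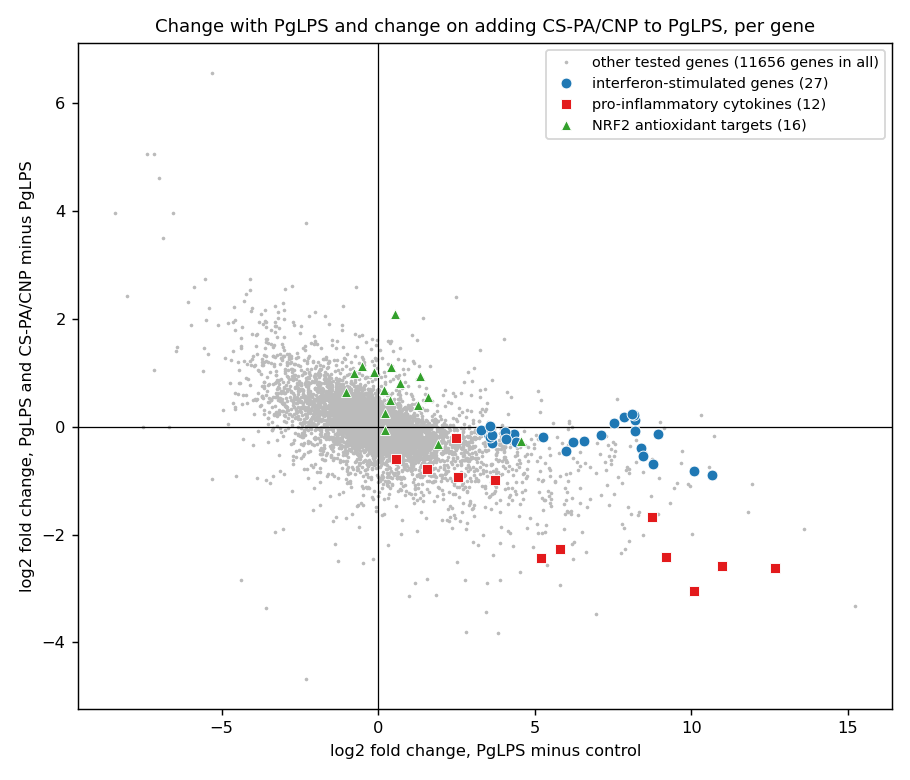
Log2 fold change of 11656 genes for PgLPS against control (horizontal) and for both against PgLPS (vertical), with 27 interferon-stimulated genes as circles, 12 cytokine genes as squares and 16 NRF2 targets as triangles. Cytokine genes had a median of −1.97 on the vertical axis, interferon-stimulated genes −0.16 and NRF2 targets 0.66.

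The comparison of CS-PA/CNP with control asks what the material changed without PgLPS. The antioxidant genes Gclm and Nqo1 and the inflammatory genes Marco and Acod1 were higher. Gclm rose by 1.39 ± 0.06, from 265 ± 4.5 to 693 ± 30.2 CPM (SD, n = 3; edgeR BH-adjusted p = 6.2e-12), and Nqo1 by 2.32 ± 0.18 (edgeR BH-adjusted p = 4.1e-08). Marco rose by 2.70 ± 0.10, from 6.68 ± 0.55 to 43.3 ± 3.3 CPM (edgeR BH-adjusted p = 5.0e-12), and Acod1 by 3.35 ± 0.15, from 2.14 ± 0.86 to 21.8 ± 1.8 CPM (edgeR BH-adjusted p = 2.9e-11). Plau fell by 1.37 ± 0.05, from 1139 ± 21.5 to 441 ± 20.6 CPM (edgeR BH-adjusted p = 6.2e-12).

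In all, 777 genes rose and 654 fell, and 107 and 62 of these changed at least 2-fold. The count of falls was 406 without CS-PA/CNP library 3 and 417 without control library 1. Other large rises were in Saa3 (3.40 ± 0.52; 2.51 without CS-PA/CNP library 3), the endothelin receptor gene Ednrb (2.65 ± 0.19), Tarm1 (2.60 ± 0.19), the arginine synthesis enzyme Ass1 (2.56 ± 0.10) and Cxcl2 (2.51 ± 0.12). Other large falls were in Nes, the nestin gene (−2.08 ± 0.16), Plxdc2 (−1.50 ± 0.09), Hdac9 (−1.42 ± 0.12), Npas4 (−1.42 ± 0.20), Sox4 (−1.39 ± 0.12), Fgf13 (−1.36 ± 0.22) and Ctnnd2 (−1.37 ± 0.31; −1.06 and not called without control library 1). Tnf rose by 0.78 ± 0.08, from 42.5 ± 2.1 to 73.2 ± 2.2 CPM (edgeR BH-adjusted p = 2.1e-06). Il1b rose by 2.82 ± 0.38 to 3.18 ± 1.5 CPM, 3.42 without control library 2 (edgeR BH-adjusted p = 4.1e-05). Il6 had 15 reads against 2 in control, a ratio of 7.22 (1.68 to 65.1; edgeR BH-adjusted p = 0.0559, 0.0212 to 0.209 over the alternatives), and was called without control library 3, at 0.0212, and with no filter on low counts. The excess over control of Saa3, Il1b and Ccl5 in these libraries, pooled over the group, was 0.0793%, 0.0927% and 0.148% of their level with PgLPS, shares so small that stray reads from the libraries with PgLPS cannot be excluded as their source. Il10 had −0.11 ± 0.22 (edgeR BH-adjusted p = 0.828) and Arg1 0.51 ± 0.39 (edgeR BH-adjusted p = 0.484). Nos2 had 3 reads in each group, too few for a fold.

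All 16 NRF2 targets rose by either adjustment, with Prdx1, a peroxiredoxin, at 1.22 and Cat at 1.06 (list median 0.91, camera BH-adjusted p = 4.6e-27). Of 19 NF-kB feedback genes 12 rose and 7 were not called, or 13 rose adjusted over the list alone, with Nfkbie at 1.19, Icam1 at 1.14 and Nfkbia at 1.09 (camera BH-adjusted p = 8.7e-12). Of 27 interferon-stimulated genes 13 rose and 14 were not called, or 17 rose adjusted over the list alone, with Ifi205 at 1.91 ± 0.23 and Rsad2 at 0.61 ± 0.11 (camera BH-adjusted p = 1.0e-09). For 10 of these 13 genes, Ifi205 and Rsad2 among them, stray reads from the libraries with PgLPS cannot be excluded as the source of the rise, and the same holds for Cxcl10 and Ccl5 among the chemokine genes and Zbp1 among the inflammasome genes. Of 16 inflammatory effectors 8 rose and 8 were not called in both adjustments, with the formyl peptide receptor Fpr1 at 2.12 and Ptges at 1.87 (camera BH-adjusted p = 1.5e-09). Of 16 chemokine genes 7 rose, 1 fell and 8 were not called in both adjustments, with Ccl5 at 2.77 ± 0.36 and Cxcl1 at 2.83 ± 0.39 (camera BH-adjusted p = 0.00667). Of 14 inflammasome genes 5 rose and 1 fell, or 7 and 1 adjusted over the list alone, with Mefv at 0.98 and Ninj1 at 0.90 (camera BH-adjusted p = 4.1e-04). Of 19 cholesterol synthesis genes 7 rose, or 8 adjusted over the list alone, with Sqle at 0.35 (camera BH-adjusted p = 4.3e-05). Of 12 growth and repair factors 7 fell and 5 were not called in both adjustments, with Hbegf at −1.67 ± 0.31 and Fn1, the fibronectin gene, at −0.97 ± 0.18 (camera BH-adjusted p = 1.2e-05).

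A further 5 lists were called with the preset correlation alone. Of 25 cell cycle genes 15 fell, or 16 adjusted over the list alone, with Mcm4 at −0.54 (camera BH-adjusted p = 5.3e-07, adjusted p = 0.141 with an estimated correlation). Of 12 cytokine genes 2 rose, or 3 adjusted over the list alone (camera BH-adjusted p = 0.00679, adjusted p = 0.140 with an estimated correlation). Of 20 genes of glycolysis and hypoxia response 10 rose and 2 fell in both adjustments, with the lactate transporter Slc16a3 at 0.76 (camera BH-adjusted p = 0.00265, adjusted p = 0.292 with an estimated correlation). Of 12 MHC class I genes 3 rose, or 8 adjusted over the list alone, with H2-K1 at 0.39 (camera BH-adjusted p = 0.00128, adjusted p = 0.292 with an estimated correlation). Of 15 stress response genes 6 rose and 3 fell, or 8 and 3 adjusted over the list alone, with Hspa5 at 0.48 and Asns at −0.56 (camera BH-adjusted p = 0.0132, adjusted p = 0.173 with an estimated correlation). Of 18 Toll-like receptor signalling genes 3 rose, with Tlr2 at 0.91, or 3 rose and 1 fell adjusted over the list alone (camera BH-adjusted p = 0.352). Of 15 alternative activation genes 1 rose and 5 fell, or 2 and 5 adjusted over the list alone, with Pparg at −0.81 and Mrc1 at −0.52 (camera BH-adjusted p = 0.0774).

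Of the genes that rose with CS-PA/CNP, 612 also rose with PgLPS, where independent lists would share 250.0, and of those that fell 518 also fell with PgLPS, against 207. In opposite directions there were 68 and 76 genes, against 246 and 210.4. Both comparisons use the same control libraries, which simulated unchanged groups turned into a covariance of 0.0183 against 0.272 observed, and a correlation across genes of 0.493 against 0.473 observed. The 3 control libraries could not be split, so part of the excess over independent lists can come from them. Of the calls with CS-PA/CNP, 54.3% were rises, and with library totals 41.9%.

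The comparison of both agents with control asks how far the treated cells stood from untreated ones. Most inflammatory and all tested interferon-stimulated genes lay above control. Saa3 was higher by 11.69 ± 0.42, at 3517 ± 360.2 CPM (SD, n = 3; edgeR BH-adjusted p = 1.7e-14), and Il1b by 10.07 ± 0.23, with 10.66 without control library 2 (edgeR BH-adjusted p = 1.1e-17). Ccl5 was higher by 10.89 ± 0.23, at 1147 ± 89.0 CPM (edgeR BH-adjusted p = 4.3e-18). Slco2b1 was lower, at −6.10 ± 0.23 (edgeR BH-adjusted p = 3.9e-14), and so was Nptx1, at −5.58 ± 0.16.

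In all, 3457 genes were higher and 3305 lower than in control, and 1138 and 1157 of these differed at least 2-fold. Serpinb2 was at least 519.4-fold, Apol9b at least 199.8-fold and Itgb8 at least 162.6-fold higher than in control, where none of the 3 had reads. Other large rises were in Cxcl3 (10.56 ± 0.35; 12.56 without control library 3 and 9.97 without control library 1) and Acod1 (9.81 ± 0.14), and another large fall was in the transcription factor gene Sox4 (−4.64 ± 0.17). Tox2 (−5.05) and Lama3 (−4.96) were also lower. Gabbr2 (−5.45 ± 0.45), Ankle1 (−5.25 ± 0.51) and Nanos1 (−4.75) had few reads with both agents, and without library 2 of both agents they stood at −7.17, −6.98 and −5.43. Tnf was higher by 2.26 ± 0.08, Il10 by 2.69 ± 0.18 and Arg1 by 4.62 ± 0.28. Il6 had 260 reads against 2, a ratio of 156.2 (42.8 to 1296), and Nos2 had 138 against 3, a ratio of 55.3 (18.5 to 271.3).

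By list, all 27 interferon-stimulated genes were higher, with Rsad2 at 8.32 ± 0.11 and a median of 6.30 (camera BH-adjusted p = 3.5e-22). So were 16 of 16 chemokine genes (camera BH-adjusted p = 1.2e-10), 15 of 16 inflammatory effectors (camera BH-adjusted p = 9.3e-11) and 11 of 12 cytokine genes (camera BH-adjusted p = 3.5e-06). Of 19 NF-kB feedback genes 18 were higher and 1 lower (camera BH-adjusted p = 1.0e-09). Of 16 NRF2 targets 14 were higher and 1 lower, with Prdx1 at 2.29 ± 0.06 and the haem oxygenase Hmox1 at 2.15 ± 0.07 (camera BH-adjusted p = 6.4e-07, adjusted p = 0.0984 with an estimated correlation). Of 15 stress response genes 11 were higher and 1 lower, with Herpud1 at 1.12 (camera BH-adjusted p = 0.00192, adjusted p = 0.0837 with an estimated correlation). All 25 cell cycle genes were lower, with Mcm5 at −2.92 (camera BH-adjusted p = 7.7e-13). All 12 MHC class I genes were higher (camera BH-adjusted p = 1.0e-08, adjusted p = 0.0837 with an estimated correlation), as were 7 of 8 MHC class II genes (camera BH-adjusted p = 0.00343, adjusted p = 0.146 with an estimated correlation). In each of these lists the counts adjusted over the list alone were the same. Of the calls, 51.1% were rises, and with library totals 21.3%. For 850 of the genes called with TMM, library totals gave a fold change of the opposite sign, whether called or not.

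The interaction asks whether CS-PA/CNP changed a gene differently with PgLPS than without. A negative value means a smaller rise or a larger fall with PgLPS. Il1b, which was higher with CS-PA/CNP than in control and lower with both than with PgLPS, had −5.44 ± 0.38 (edgeR BH-adjusted p = 6.2e-09; −6.03 without control library 2). Saa3 had −5.30 ± 0.55 (edgeR BH-adjusted p = 1.1e-06; −4.41 without CS-PA/CNP library 3) and Tnf −0.999 ± 0.11 (edgeR BH-adjusted p = 3.4e-06). The values of Il1b and Saa3 include their rise with CS-PA/CNP alone, an excess of 0.0927% and 0.0793% of their level with PgLPS, for which stray reads from the libraries with PgLPS cannot be excluded, as for the rise of Ifi205 and of 9 other interferon-stimulated genes. Nptx1, lowered alone and raised with PgLPS, had 3.47 ± 0.39 (edgeR BH-adjusted p = 2.6e-06), and Plau, also lowered alone, had 2.60 ± 0.08 (edgeR BH-adjusted p = 3.2e-13). In all, 869 genes had a positive and 972 a negative interaction, and 245 and 278 of these were at least 2-fold.

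Other genes with large positive values were Klhl3 (3.79 ± 0.59), Plekhh2 (3.35 ± 0.58; 3.94 without PgLPS library 2), Dmpk (2.97 ± 0.58; 2.16 without library 1 of both agents), Npas4 (2.89 ± 0.34) and Cmbl (2.76 ± 0.53; 3.41 without PgLPS library 1). Il6 had −5.68 ± 0.85 (edgeR BH-adjusted p = 8.1e-05; −8.23 without control library 3). Serpinb2 (−8.08 ± 1.83) and Itgb8 (−6.94 ± 1.52) had no control reads, so those 2 values and that of Il6 depend on the prior count of the fit. The level of Serpinb2 with CS-PA/CNP alone was 0.0668% of its level with PgLPS, so stray reads cannot be excluded for it either. On the positive side, the 3 PgLPS libraries held 0, 2 and 2 reads of Klhl3, 2, 4 and 1 of Plekhh2 and 5, 3 and 1 of Cmbl. They held 6, 2 and 7 reads of Nptx1 and 6, 5 and 9 of Dmpk, so these positive values also rest on few reads. Arg1 had −1.53 ± 0.43 (edgeR BH-adjusted p = 0.0197, 2.1e-05 to 0.116 over the alternatives). Its call was lost without control library 2 (−1.28), control library 3 (−1.39) or CS-PA/CNP library 3 (−1.28) and by limma-voom. Il10 had 0.56 ± 0.27 (edgeR BH-adjusted p = 0.189) and Nos2 −2.23 ± 1.44 (edgeR BH-adjusted p = 0.369).

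Of 12 cytokine genes 9 had a negative interaction, or 10 adjusted over the list alone (camera BH-adjusted p = 1.0e-10). The same held for 15 of 19 NF-kB feedback genes, or 17, with Nfkbia at −1.71 (camera BH-adjusted p = 3.2e-17), and for 13 of 16 inflammatory effectors, or 14, with Acod1 at −4.09 ± 0.18 and Marco at −2.95 ± 0.13 (camera BH-adjusted p = 3.8e-16). It held for 9 of 16 chemokine genes, or 10, with Cxcl2 at −2.90 ± 0.16 (camera BH-adjusted p = 2.1e-06), and for 15 of 27 interferon-stimulated genes, or 20, with Ifi205 at −2.72 (camera BH-adjusted p = 7.4e-09). It held for 6 of 18 Toll-like receptor signalling genes, or 8 (camera BH-adjusted p = 3.9e-04), and for 8 of 14 inflammasome genes, or 9, with 1 positive in each adjustment (camera BH-adjusted p = 1.1e-04). In each of these the second number is adjusted over the list alone. Of 12 growth and repair factors 4 were positive and 1 negative, or 6 and 1 adjusted over the list alone, with Pdgfb at 1.36 (camera BH-adjusted p = 0.00592).

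A further 6 lists were called with the preset correlation alone. Of 20 genes of glycolysis and hypoxia response 12 were negative and 1 positive, or 12 and 2 adjusted over the list alone, with Pfkfb3 at −1.98 (camera BH-adjusted p = 2.1e-06, adjusted p = 0.111 with an estimated correlation). Of 12 MHC class I genes 9 were negative, or 10 adjusted over the list alone (camera BH-adjusted p = 2.8e-05, adjusted p = 0.176 with an estimated correlation). Of 25 cell cycle genes 12 were positive and 1 negative, or 13 and 1 adjusted over the list alone, with Pcna at 1.07 (camera BH-adjusted p = 5.3e-05, adjusted p = 0.186 with an estimated correlation). Of 16 NRF2 targets 7 were negative and 2 positive, or 8 and 2 adjusted over the list alone, with Gsr at −1.18 (camera BH-adjusted p = 0.00277, adjusted p = 0.284 with an estimated correlation). Of 15 matrix proteases and inhibitors 6 were negative and 2 positive, or 7 and 2 adjusted over the list alone, with the membrane collagenase Mmp14 at −2.02 (camera BH-adjusted p = 0.0443, adjusted p = 0.111 with an estimated correlation). That list lost its call without PgLPS library 1 (0.0582) and without library 2 (0.0664) or 3 (0.0574) of both agents and with the stricter filter (0.107), as camera BH-adjusted p, and by fry (BH-adjusted p = 0.0856). Of 5 tested vasoactive genes 2 were negative, or 3 adjusted over the list alone (camera BH-adjusted p = 0.0491, adjusted p = 0.123 with an estimated correlation). Of the calls of the interaction, 47.2% were positive, and with library totals 63.7%.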

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

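The interaction test and the splits of the libraries were fixed in advance, and every other test in this part was chosen after the results were seen. The permutation tests and random lists below resample genes, not libraries. Their p-values and percentiles treat genes that move together as independent and do not measure the spread between libraries. The interaction singled out genes whose log2 change with CS-PA/CNP differed with and without PgLPS: 869 with a positive and 972 with a negative value. Of the negative ones, 936 rose with PgLPS and 7 fell, and of the positive ones 795 fell and 38 rose. The interaction and the PgLPS comparison share the PgLPS and control libraries with opposite sign, so part of this overlap can come from them. A difference in log2 change does not by itself show that CS-PA/CNP acted differently, and limits on how far a gene can change were not tested. The genes named for the largest log2 values were Klhl3 (3.79), Nptx1 (3.47), Plekhh2 (3.35), Dmpk (2.97), Npas4 (2.89) and Cmbl (2.76) on the positive side and Serpinb2 (−8.08), Itgb8 (−6.94), Il6 (−5.68), Il1b (−5.44) and Saa3 (−5.30) on the negative side. Edn1, the endothelin-1 gene, had −4.99 ± 1.56 (edgeR BH-adjusted p = 0.0391), and its call was lost in 9 of the 12 fits that left out 1 library: each control and each CS-PA/CNP library, PgLPS library 2, PgLPS library 3 and library 2 of both agents. The edgeR BH-adjusted p of Edn1 ranged from 0.00595 to 0.0866 over the alternatives. Tnf (−0.999) and Arg1 (−1.53) were also called; Arg1 was not called without control library 2 (−1.28), control library 3 (−1.39) or CS-PA/CNP library 3 (−1.28). Serpinb2, Itgb8 and Edn1 had 0 control reads and Il6 had 2, so their fitted values depend on the prior count and bound nothing. Klhl3, Plekhh2 and Cmbl had 0 to 5 reads per PgLPS library, and Nptx1 and Dmpk had 2 to 9. The positive values of these genes therefore rest on few reads.

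Of 100 reassignments of the CS-PA/CNP label drawn within the libraries with and without PgLPS, the real one included, 1 gave as many genes. It was the real one, with 1841 genes with an interaction, and the highest other had 574. Every other draw mixed libraries with and without CS-PA/CNP in a group, so the effect of CS-PA/CNP itself widened the spread and lowered the count. The draws thus address the absence of any CS-PA/CNP effect and do not exclude chance for the interaction. For each of the 4 comparisons of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, with 7149 genes for PgLPS against control, 1743 for both against PgLPS, 1982 for CS-PA/CNP against control and 6608 for both against control in fits of those 6 libraries, and 0 in the highest other split.

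The first pattern is that 612 genes raised by PgLPS were also higher with CS-PA/CNP alone. Reads of PgLPS libraries that strayed into the CS-PA/CNP libraries are argued against as the whole cause: after the median share that abundant PgLPS genes would need (0.313%) was taken off, 94.61% of the genes stayed called. Saa3, Il1b and Ccl5 alone would need at most 0.1484% of such reads, less than the lower quartile of the needed shares (0.160%), so for these genes a stray share cannot be told apart from expression. The same holds for interferon-stimulated genes: the 6 libraries with PgLPS, each giving all its genes at 1 share, can send no more than the reads that the CS-PA/CNP libraries hold of every gene, and only 23.08% of the 13 called interferon-stimulated genes had an excess beyond that limit (Oas2, Ddx58 and Gbp2), against 97.4% of the 612 genes. With library totals 396 genes were called higher in both, 3.884 times the number for independent lists. Both comparisons use the same control libraries, which can raise this ratio under any scaling, so it does not decide on library scaling. A first bound, that 90% of the 612 keep their call, was not met (489, or 79.9%), and the ratio was chosen after it. An evenly scaled-down PgLPS response is argued against by the 15.76 points between the median shares of the PgLPS change seen in NF-kB feedback genes (22.7%, 18 genes) and interferon-stimulated genes (6.98%, 27 genes; permutation p = 0.00013); its name was narrowed after that value was seen, and a lower dose of a similar stimulus with unequal responses, or an effect of the material itself, may explain the pattern and stays open.

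The second pattern is that cytokine genes were lowered more than interferon-stimulated genes when CS-PA/CNP was added to PgLPS, although 11 of 27 of the latter also fell. Fewer PgLPS-responding cells would lower both alike only if each cell responded without signals from other cells, which was not tested. The interferon-stimulated genes kept a median of 89.6% of the PgLPS rise and the cytokine genes 19.1%. These medians lay 70.45 points apart (permutation of genes, p = 1e-05, the smallest the resamples can give). The gap argues against fewer responding cells only under that condition. The size of the PgLPS induction and the expression level are argued against by 10000 random lists matched on both: the interferon-stimulated median of −0.16 lay at percentile 100 of its matched lists, and the cytokine median of −1.97 at percentile 0 of its own. Library scaling is argued against because 1 factor per library moves all genes alike, whereas the median log2 fold changes of these lists lay 1.816 apart (permutation p = 1e-05). A hypothesis that stays is that CS-PA/CNP may act on the cytokine arm of the PgLPS response more than on the interferon arm, found and tested on the same data. A weaker PgLPS stimulus with unequal responses of the genes could give the same gap, was not tested and also stays open.

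The third pattern is that library totals moved the median log2 fold change of all genes by −0.41 with PgLPS. A few induced genes taking the reads may explain part of it: leaving out the 100 genes with the largest gain, which held 19.4% of reads with PgLPS and 5.50% in control, removed 55.42% of the shift. Leaving out the 1000 genes with the largest gain, with 42.9% and 17.8% of reads, turned the shift to 0.11. These genes were chosen for their gain, so that leaving them out shrinks the shift by construction and decides nothing. Total RNA per cell was not measured, so a real loss of most messengers and the uptake of reads by induced genes cannot be told apart.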

How the results depend on the processing

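The settings chosen after the data were seen are the replicate block by column number and, for the lists, DESeq2 size factors and library totals. With library totals in place of TMM, PgLPS against control gave 1945 rises and 6963 falls and both against control 1808 and 6685; this setting moves all genes of a library together. Requiring at least 2-fold gave 1372 and 1468 for PgLPS against control, 152 and 203 for both against PgLPS, 107 and 62 for CS-PA/CNP against control, 1138 and 1157 for both against control and 245 and 278 for the interaction, with 290 reversed genes, by construction fewer. Leaving out 1 library gave 3384 to 3659 rises and 3372 to 3634 falls for PgLPS against control, 903 to 1117 and 966 to 1233 for both against PgLPS, 543 to 622 and 406 to 518 for CS-PA/CNP against control, 3126 to 3339 and 3009 to 3179 for both against control, 728 to 854 and 783 to 991 for the interaction, and 1548 to 1895 reversed genes over the control, PgLPS and combined libraries. The fall of the CS-PA/CNP count of 654 lower genes to 406 without CS-PA/CNP library 3 and 417 without control library 1 came with fewer libraries in the fit; the cause was not tested. Estimated correlations left 7, 6, 8 and 8 called lists for PgLPS against control, both against PgLPS, CS-PA/CNP against control and the interaction, and fry, which asks only whether a list moves one way, called 27 for PgLPS against control and 25 for both against control. The osteoclast list for both against control turned from down by camera to up by fry (fry BH-adjusted p = 0.0127); the cause was not tested.

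Of 145 list results, 117 kept their direction and side of the threshold with estimated correlations and 28 lost the call; with DESeq2 size factors 145 kept both, with library totals 137. Of 1044 list results with 1 library left out, 1014 kept direction and side of the threshold, 10 lost the call and 20 gained one. Of 649 results of named genes, 647 kept both with DESeq2 size factors, 629 with library totals, 635 with no filter, 636 with the DESeq2 test and 639 with limma-voom; of 4656 with 1 library left out, 4525 kept both, 100 lost the call and 31 gained one. Genes changed 1.3-fold in simulation were recovered at 46% for CS-PA/CNP against control among 11530 genes and 18% for the interaction, so small changes are often missed at this depth and number of libraries.

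The planned block by the replicate number of the sample titles was not run, because these numbers could not be matched to the count columns. The replicate block by column number called 7809 genes for PgLPS against control, 2905 for both against PgLPS, 2033 for CS-PA/CNP against control, 7166 for both against control and 2403 for the interaction, where the fit without it called 7433, 2268, 1431, 6762 and 1841, and 2329 reversed genes. With the block the interaction of the matrix protease list (camera BH-adjusted p = 0.0609) and of the vasoactive list (0.0609) and the stromal list for both against PgLPS (0.0603) were not called, 3 other list results were gained, and of 649 results of named genes 28 were gained, among them Tnf for both against PgLPS (edgeR BH-adjusted p = 0.0142), and 0 lost. Of 18 pairs of libraries with the same number, 4 had a correlation of their deviations over 0.1 and 15 over 0 (range −0.068 to 0.224), and 6 of 12 libraries correlated best with their own number. Pairs with different numbers ranged from −0.190 to 0.108, so the 4 same-number correlations over 0.1 lay above all of them. The numbers were not taken to pair samples, since not every pair passed 0.1, but a pairing of some libraries is not excluded. If they do pair samples, the fit without the block ignores that pairing. Alternative pseudocounts were planned only for normalized values and were not run.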

Other observations

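The tests in this part were fixed in advance, and the groups to describe were chosen after the results were seen. Of the endothelin system, which acts on vessel tone, the receptor gene Ednrb and the ligand gene Edn1 both rose with PgLPS, and adding CS-PA/CNP raised the first and lowered the second. Of 22 genes on the vasoactive list only 5 passed the filter. Ednrb, the endothelin B receptor gene, lay at 1.84 ± 0.70 CPM in control, 11.4 ± 1.7 with CS-PA/CNP, 29.6 ± 1.8 with PgLPS and 91.2 ± 8.4 with both (SD, n = 3), so that CS-PA/CNP raised it with PgLPS by 1.62 ± 0.12 (edgeR BH-adjusted p = 1.4e-08), less than without (interaction −1.03 ± 0.24, edgeR BH-adjusted p = 4.6e-03). Edn1 had 0 reads in control, 3 with CS-PA/CNP, 338 with PgLPS and 89 with both. It was at least 141.8-fold higher with PgLPS than in control, and adding CS-PA/CNP lowered it by a log2 fold change of −1.98 ± 0.25 (edgeR BH-adjusted p = 2.1e-05). Of the 5 genes 4 rose with PgLPS, in both adjustments (camera BH-adjusted p = 0.0392, adjusted p = 0.117 with an estimated correlation), and 1 rose and 1 fell when CS-PA/CNP was added, in both adjustments (camera BH-adjusted p = 0.289).

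Genes of lipid handling and of the lysosome split into both directions. Lipa, the lysosomal acid lipase gene, went from 2364 ± 16.7 CPM in control to 743 ± 14.7 with PgLPS and 1766 ± 50.7 with both, a rise of 1.25 ± 0.05 on adding CS-PA/CNP. The fatty acid transporter Cd36 fell with PgLPS (−0.91 ± 0.05) and rose on adding CS-PA/CNP (0.74 ± 0.05), and the cholesterol exporter Abca1 did the opposite (2.77 ± 0.11 and −0.90 ± 0.10). Of 20 lysosome genes 8 rose and 12 fell with PgLPS in both adjustments (camera BH-adjusted p = 0.338), and 7 rose and 5 fell on adding CS-PA/CNP, or 8 and 5 adjusted over the list alone (camera BH-adjusted p = 0.234). Of 15 lipid handling genes 4 rose and 8 fell with PgLPS in both adjustments, with a median of −0.33 and a mean of 0.09 (camera downward, BH-adjusted p = 0.302), and 6 rose and 3 fell on adding CS-PA/CNP, or 7 and 3 adjusted over the list alone (camera BH-adjusted p = 0.114). Of 15 matrix proteases and inhibitors 10 rose and 4 fell with PgLPS in both adjustments, with the collagenase Mmp13 at 6.05 ± 0.10 (camera BH-adjusted p = 0.0844). On adding CS-PA/CNP 3 rose and 6 fell in both adjustments, with Mmp13 at −1.58 ± 0.08 (camera BH-adjusted p = 0.118). Of 12 osteoclast genes 4 rose and 7 fell with PgLPS in both adjustments, with Acp5, the tartrate-resistant phosphatase gene, at 3.81 ± 0.11 and a median of −0.47 beside a mean of 0.05 (camera downward, BH-adjusted p = 0.343). On adding CS-PA/CNP 4 rose and 2 fell in both adjustments, with Car2, a carbonic anhydrase gene, at −1.51 ± 0.24 (camera BH-adjusted p = 0.201).

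Cholesterol synthesis, called on adding CS-PA/CNP, was not called for PgLPS against control, where 5 of 19 rose and 4 fell, or 4 and 4 adjusted over the list alone, with a median of 0.01, a mean of −0.03 and a downward test (camera BH-adjusted p = 0.921). Of 11 p53 targets 6 rose and 3 fell with PgLPS, or 6 and 4 adjusted over the list alone, with the death receptor gene Fas at 3.90 (camera BH-adjusted p = 0.343). Of 13 macrophage identity genes 8 rose and 4 fell, or 8 and 5 adjusted over the list alone, with the Fc receptor gene Fcgr1 at 3.54 and the fractalkine receptor gene Cx3cr1 at −3.22 (camera BH-adjusted p = 0.195). Growth and repair factors on adding CS-PA/CNP gave 2 rises and 2 falls, or 3 and 3 adjusted over the list alone, with Pdgfb at 1.12 ± 0.08 and Fn1 at −0.91, or −0.56 without PgLPS library 1 (camera BH-adjusted p = 0.837).

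In control, tested markers of stromal, B, dendritic, erythroid, and mast cells and basophils were low, but several neutrophil markers and the T cell marker Il7r were not. The control libraries held 795, 813 and 820 reads of Ngp, 1115, 1053 and 1214 of S100a9 and 910, 901 and 883 of Csf3r. They held 5540, 5795 and 4813 of Il7r. The neutrophil markers Camp, Cxcr2, Mpo and Retnlg had 8 to 47 reads per control library. These genes are named for their reads, outside the rule, and the source of the reads was not tested. PgLPS library 1 held 296 reads of Col1a2 against at most 48 in any other library, 43 of Col3a1 against at most 4 and 70 of Postn against at most 26. Without that library the falls of Col1a1 (−2.90 ± 0.75) and Col1a2 (−3.83 ± 0.99) on adding CS-PA/CNP were −1.03 and −1.55 and no longer called, and neither was called by limma-voom, whereas Pdgfrb had 64, 41 and 57 reads in the PgLPS libraries and 12, 13 and 12 with both. Of 9 neutrophil markers 4 rose and 1 fell with PgLPS, or 4 and 0 adjusted over the list alone, with the receptor gene Csf3r at 3.41 ± 0.06 (camera BH-adjusted p = 0.233). On adding CS-PA/CNP 2 fell, or 3 adjusted over the list alone, with Csf3r at −1.11 ± 0.05 (camera BH-adjusted p = 0.0298, adjusted p = 0.328 with an estimated correlation, 0.0627 without PgLPS library 2 and 0.0970 without library 2 of both agents). With PgLPS, counts by either adjustment were 1 rise and 2 falls among 3 T cell markers (camera BH-adjusted p = 0.343), no call among 4 B cell markers (camera BH-adjusted p = 0.726), 2 rises among 3 dendritic cell markers (camera BH-adjusted p = 0.277) and 2 rises among 6 mast cell and basophil markers, with the histidine decarboxylase gene Hdc at 5.53 ± 0.26 (camera BH-adjusted p = 0.302). The single tested erythroid marker, Epor, had −0.44 ± 0.57 (edgeR BH-adjusted p = 0.519).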
